A study of Mus musculus with 4 samples.

How the data were processed

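The data are signals from 4 Affymetrix arrays hybridised with biotin-labelled total RNA of whole embryonic mouse lung, 2 wild type and 2 Sftpc-Nmyc. RNA was purified with an RNeasy kit and labelled with an Affymetrix kit, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, for 22690 probe sets. The software, background correction and scaling behind them are not given in the sources used here. The values themselves show that each array has the same mean of 150.05 once the highest and lowest 2% are left out, as scaling of each array to a common level would give. Scanner files and detection calls were not used here, so whether a probe set was called present is unknown. As a guide to background, the highest signal among 27 Bacillus control probe sets was 73.4, although whether these were spiked in is not given.

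Probe sets were named from the platform annotation supplied with the value table, with symbols checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 64 were controls, 20380 had 1 symbol, 691 had several and 1555 had none. By identifier 20351 matched and 0 symbols needed updating. Only probe sets with 1 symbol entered the tests. No genome sequence or probe sequence was used, so the position of a probe set in its transcript is unknown and no coordinates are given.

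Values under 1 were set to 1, an offset of 5 (the 10th percentile of all values) was added, the base-2 logarithm was taken, and the 4 arrays were quantile normalized over the non-control probe sets. All fold changes are on that log2(value + 5) scale, which understates changes of dim genes. For each of 12393 genes the probe set with the highest mean over all 4 arrays stood for the gene, and 4956 genes had more than 1. Of 1298 called genes with more than 1 probe set, 4 had another probe set that passed in the opposite direction, Mycn and, named after their values were seen, Hnrnpab, Polr2f and Rsrp1. Genes whose mean over all arrays lay below the 30th percentile were left out, leaving 8675. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of variance on mean), with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Errors after ± are limma standard errors unless marked SD, and the median standard error was 0.19.

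Of 48 gene lists written before the data were examined, the 39 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the data and limma's directional fry test stand beside it. With an estimated correlation, camera has little power on 4 arrays. Ribosome biogenesis, at an estimated correlation of -0.020, below the preset 0.01, went from an unadjusted camera p of 1.2e-17 to 0.010. Not passing there thus does not decide whether a list rests on correlation between its genes. Estimated correlations over the 39 lists ran from -0.12 (ciliated cell) to 0.64 (G2/M and mitosis). They were 0.41 for alveolar type II, 0.31 for alveolar type I, 0.50 for S phase and 0.50 for cardiac muscle. For lists this far above the preset 0.01, the camera p-values at the preset value may be too small. Camera compares a list with the other genes, and fry asks whether the list's genes move on balance in 1 direction. Medians of 6 pairs of lists were compared by permuting members between the lists (100000 resamples, two-sided), where genes and not animals are the units. These pairs were chosen after the medians were seen, and the 2 with the pan-epithelial list were added last. Lists with fewer than 5 tested members were basal and stratified epithelium, intestinal epithelium, lymphocyte and thymus, skeletal muscle, cartilage, liver, adipose, sex-linked, and genes that differ between C57BL/6J and DBA/2J. In these 9 lists, 1 gene was higher (Krt15) and 6 were lower (Thy1, Ckm, Alb, Lipe, Xist and Hc). Of these, Lipe was not called whichever of the 4 arrays was left out (limma adjusted p = 0.060 to 0.16), nor Alb without either wild-type array or transgenic replicate 1 (0.076 to 0.10), Krt15 without wild-type replicate 2 (0.14) or transgenic replicate 1 (0.11), and Thy1 without wild-type replicate 2 (0.059).

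The genes named were fixed by rule before the data were examined. They are Mycn, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, up to 4 members of each list with the largest moderated statistic, and up to 2 members that go most against the direction of a list that passed or of 6 chosen lists. Genes without an official-style symbol were passed over and sex-linked genes were kept to their own list. The rule gave 213 names, of which 163 passed. Names outside the rule are marked where they appear.

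The code was tested on simulated data for the same comparison of 2 arrays with 2, over 8675 genes. With 200 genes changed, 100 per size, 51% of the 2-fold and 91% of the 4-fold changes were recovered, and 6 of 148 calls were unchanged genes. With no change anywhere, 0 genes and 0 of 39 lists passed. Each simulated gene was drawn independently, so the 0 lists say nothing on lists whose genes move together. In the data 30.4% of tested genes were called, far more than were changed here, so the recovery rates may not carry over.

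Alternatives fixed beforehand were the authors' scaling alone, scaling to the 75th percentile, cyclic loess, offsets of 1 and 20.8 (the 25th percentile), no variance trend, the replicate number as a block, no filter on dim genes or a filter at the 50th percentile, the mean of a gene's probe sets, all probe sets, an adjusted p under 0.1, a 2-fold minimum, the other list tests, and each array left out in turn. Autosomal genes alone, and the 7413 genes above the Bacillus controls in at least 1 group, were added after the data were seen. Splits of the samples into other groups and tests for outlying arrays need larger groups and were not made. The labels give no scan dates, batches or sex. The design text calls the duplicates biological replicates, and p-values rest on 2 arrays per group.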

Results

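Expression was measured in whole lungs of mouse embryos on 4 Affymetrix arrays, 2 from wild-type embryos and 2 from embryos carrying an Sftpc-Nmyc transgene. The transgene joins mouse Nmyc1 (Mycn in current nomenclature, a transcription factor of the MYC family that drives growth and division) to the fluorescent protein EGFP. It is driven by 3.7 kb of the human SFTPC promoter, which is active in lung epithelium. The titles of all 4 samples give embryonic day 18, shortly before birth. The design text gives a slightly later time for the transgenic embryos and none for the wild type, so whether the groups were matched in age within that day is not settled by the labels. The duplicates are biological replicates per the design text, which describes the transgenic embryos as products of pronuclear injection into eggs of mixed C57BL/6J and DBA/2J background. Each array gave a signal for 22690 probe sets, with a median between 65.45 and 70.8. Over all non-control probe sets, arrays of 1 group correlated at r = 0.965 (wild type) and r = 0.968 (transgenic), and arrays of different groups at r = 0.922 to 0.933. The comparison of the 2 groups asks what misexpression of Nmyc changes in the lung. The number of arrays limits its precision, and an apparent difference in sex between the groups, described below, cannot be separated from genotype.

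Sftpc-Nmyc lungs had higher levels of genes for DNA replication, ribosome assembly and nucleotide synthesis, and lower levels of genes that mark differentiated alveolar cells, vessels and connective tissue. These lists passed in limma's camera with a preset correlation, but 0 of 39 passed with an estimated correlation (lowest adjusted p = 0.31 with an estimated correlation). The latter version has little power on 4 arrays, so it cannot decide whether correlation between genes accounts for the lists. Xist and Y-linked signals also differed between the groups. The median log2 fold change, transgenic minus wild type, was 1.54 over 27 genes of S phase and 1.21 over 34 genes of ribosome biogenesis. It was -2.68 over 20 genes of alveolar type II cells, the cells that make surfactant, and -1.14 over 19 genes of alveolar type I cells, the thin cells of gas exchange. General epithelial genes did not fall with them as a list: their median was 0.36 over 17 genes, of which 10 did not pass. Epcam, an adhesion molecule of epithelia, rose by 1.48 ± 0.12 (log2, SE, n = 2 per group). Of 8675 genes tested with limma, 2636 differed at an adjusted p under 0.05, with 1276 higher and 1360 lower in the transgenic lungs. Of these, 480 were higher and 522 lower by at least 2-fold, and 37 and 63 by at least 4-fold. All 2636 had groups that did not overlap, which follows from a call at this threshold with 2 arrays per group and is no separate support. Of all tested genes, 5906 (68.1%) had groups that did not overlap, against 33.3% expected by chance for 2 arrays against 2. The count was 1617 without wild-type replicate 1, 1375 without wild-type replicate 2 and 1618 without transgenic replicate 2.

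The misexpressed gene itself was read by 3 probe sets. Probe set 1425922_a_at rose from deposited signals of 34.7 and 32.1 in wild type to 455.2 and 356 in the transgenic lungs, a log2 fold change of 3.46 ± 0.19 for Mycn (SE; limma adjusted p = 7.3e-05). Probe set 1417155_at went the other way, from 78.7 and 63.5 to 25.1 and 27.2, a log2 fold change of -1.20 ± 0.27 (limma adjusted p = 0.016 over all probe sets). Probe set 1425923_at did not pass, at 0.64 ± 0.45 (limma adjusted p = 0.34). With the mean of the 3 probe sets in place of the brightest, Mycn stood at 0.97 (limma adjusted p = 0.025). Which of these lie inside the transgene's cDNA was not determined here, so the first does not by itself separate transgene from endogenous transcript. Most of these readings lay below 73.4, the highest signal of the 27 Bacillus control probe sets. Max, the obligate partner of MYC proteins, fell by 1.10 ± 0.20, a call that ended without wild-type replicate 2 (-1.05, limma adjusted p = 0.0501). Among 11 genes of the MYC network tested, 1 was higher and 1 was lower, and the same 1 and 1 adjusted over the list alone, and as a list they did not pass (limma camera adjusted p = 0.97).

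**Figure D1:**
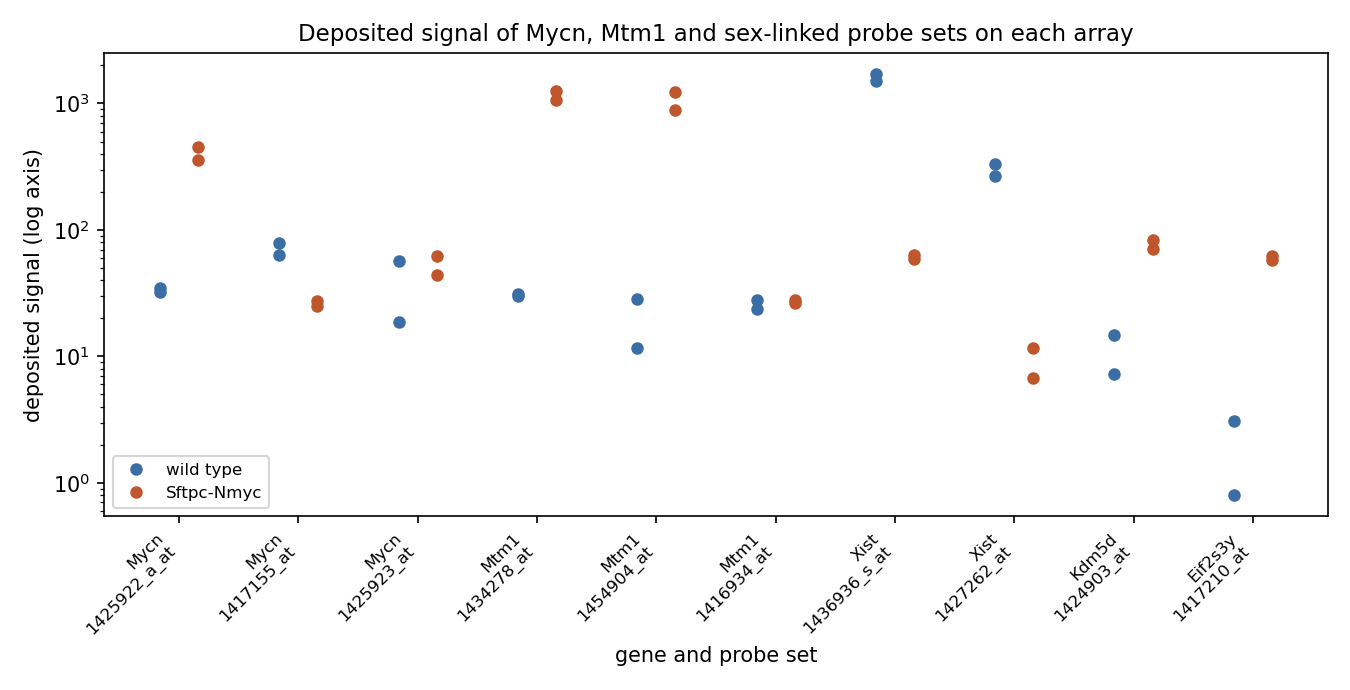
Deposited signal (log axis) of probe sets for Mycn, Mtm1, Xist and 2 Y-linked genes, each point 1 array, with wild type in blue and Sftpc-Nmyc in orange. Mycn probe set 1425922_a_at reads 455.2 and 356 in the transgenic lungs against 34.7 and 32.1 in wild type, and Xist probe set 1436936_s_at reads 59.3 and 63.9 against 1707.8 and 1506.1.

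Growth and division genes rose as groups. In S phase and DNA replication, 26 of 27 genes were higher and none lower (27 adjusted over the list alone), with a limma camera adjusted p of 1.0e-15 and an adjusted p = 0.33 with an estimated correlation. Uhrf1, which maintains DNA methylation behind the replication fork, rose by 2.50 ± 0.20, Cdt1, which licenses replication origins, by 2.30 ± 0.20, and Rfc5, a clamp loader subunit, by 2.26 ± 0.17. In G2/M and mitosis, 13 of 26 genes were higher and none lower (17 adjusted over the list alone), with a median of 0.72, a limma camera adjusted p of 7.2e-07 and an adjusted p = 0.40 with an estimated correlation. Bub1b, a spindle checkpoint kinase, rose by 1.47 ± 0.19 and Cdk1, the mitotic kinase, by 1.05 ± 0.19. The S phase median exceeded the G2/M median by 0.83 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, and 3e-05 adjusted over 6 such comparisons). In all 6 comparisons genes are the units, and genes that move together count as independent. Their p-values therefore do not measure variation between lungs. Among 6 cyclin-dependent kinase inhibitors, 3 were lower and 1 higher, also adjusted over the list alone: Cdkn2b fell by 2.00 ± 0.26 and Cdkn1a fell by 1.02 ± 0.18, while Cdkn1c rose by 1.19 ± 0.13. As a list the inhibitors did not pass (limma camera adjusted p = 0.29).

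Ribosome biogenesis had 31 of 34 genes higher and none lower (32 adjusted over the list alone), with a limma camera adjusted p of 2.4e-16 and an adjusted p = 0.31 with an estimated correlation. Nhp2 and Fbl, proteins that guide modification of ribosomal RNA, rose by 2.05 ± 0.13 and 2.00 ± 0.17, and Npm1, the abundant nucleolar chaperone, rose from a normalized signal of 1129 ± 33.2 to 3192 ± 50.5 (SD, n = 2). In nucleotide, one-carbon and polyamine synthesis, 16 of 21 were higher and none lower (17 adjusted over the list alone), with a median of 1.15, a limma camera adjusted p of 1.5e-09 and an adjusted p = 0.31 with an estimated correlation. Shmt2, the mitochondrial serine hydroxymethyltransferase, rose by 1.99 ± 0.14 and Odc1, the first enzyme of polyamine synthesis, by 1.80 ± 0.13. Of 18 translation factors 10 were higher and 1 lower, also adjusted over the list alone (median 0.49, limma camera adjusted p = 0.00012, and adjusted p = 0.31 with an estimated correlation). Pabpc4 rose by 1.75 ± 0.14. Cytosolic ribosomal proteins moved less: 12 of 42 were higher and none lower (15 and 1 adjusted over the list alone), with a median of 0.19, a limma camera adjusted p of 0.00021 and an adjusted p = 0.31 with an estimated correlation. Rpl11 rose by 1.06 ± 0.10. The ribosome biogenesis median exceeded that of the ribosomal proteins by 1.02 (two-sided permutation p = 1e-05, the smallest possible, and 3e-05 adjusted over the 6 comparisons). The ribosomal protein list is less complete, with 42 of its 75 genes measured by a probe set with 1 symbol, against 35 of 38 for ribosome biogenesis.

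**Figure D2:**
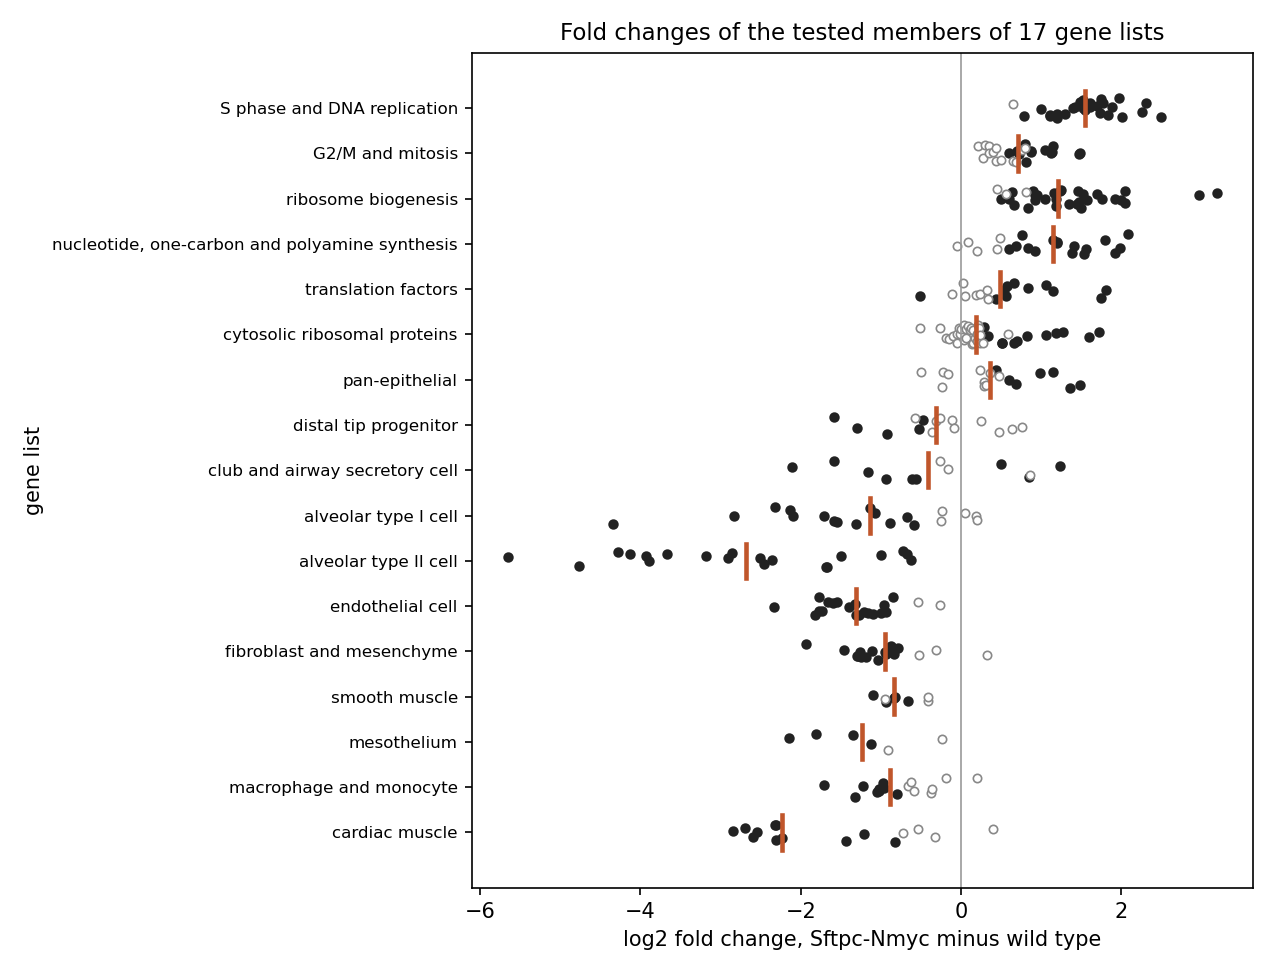
Log2 fold change, Sftpc-Nmyc minus wild type, of each tested member of 17 gene lists, with filled points for genes at a limma adjusted p under 0.05, open points for the others and an orange bar at the list median. The S phase median lies at 1.54 and the alveolar type II median at -2.68.

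All 20 tested genes of alveolar type II cells fell (20 adjusted over the list alone), with a limma camera adjusted p of 5.4e-17 and an adjusted p = 0.31 with an estimated correlation. Scd1, the desaturase that makes monounsaturated fatty acids, went from a normalized signal of 3513 ± 755 to 65.3 ± 19.1 (SD, n = 2), a log2 fold change of -5.65 ± 0.22 (SE). Slc34a2, the phosphate transporter of these cells, fell by 3.90 ± 0.18 and the chemokine Cxcl15 fell by 4.13 ± 0.20. Of the surfactant proteins named after their values were seen, Sftpc fell by 0.997 ± 0.10 and Sftpb fell by 2.85 ± 0.17. Hc, complement component 5, fell by 4.76 ± 0.46 and is also on a list of genes that differ between C57BL/6J and DBA/2J, since DBA/2J carries a deficient allele, and the alleles of these embryos are not given. Chil1, a chitinase-like protein, fell by 3.67 ± 1.03, but its normalized signal was 69.9 and 1074 on the wild-type arrays, and the call ended without wild-type replicate 2 (-1.74, limma adjusted p = 0.11) or without transgenic replicate 2 (-3.09, limma adjusted p = 0.13). In surfactant lipid synthesis 8 of 18 genes were lower and 1 higher (9 and 1 adjusted over the list alone), with a median of -0.40, a limma camera adjusted p of 0.0018 and an adjusted p = 0.33 with an estimated correlation. Lpcat1, which makes dipalmitoyl phosphatidylcholine, fell by 1.69 ± 0.10. Scd1 and Lpcat1, the largest falls of this list, are also on the alveolar type II list, so the lists are not independent.

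Of 19 alveolar type I genes 14 were lower and none higher, also adjusted over the list alone (limma camera adjusted p = 7.2e-08, and adjusted p = 0.33 with an estimated correlation). Aqp5, a water channel, fell by 4.35 ± 0.17 to a level below the Bacillus controls, and Ager, a receptor abundant on these cells, fell by 1.59 ± 0.14. Sema3a and Igfbp2 did not pass, at 0.20 ± 0.21 and 0.19 ± 0.22. The type II median differed from the type I median by -1.54 (two-sided permutation p = 0.0037, also after adjustment over the 6 comparisons). In the glucocorticoid response list, 11 of 14 were lower and none higher (12 adjusted over the list alone), with a median of -1.01, a limma camera adjusted p of 7.1e-05 and an adjusted p = 0.31 with an estimated correlation. The 3 epithelial sodium channel subunits that clear lung liquid were among them, with log2 fold changes of -1.86 ± 0.17 for Scnn1g, -1.66 ± 0.23 for Scnn1a and -1.36 ± 0.20 for Scnn1b. Mt1 and Mt2 went against the list without passing, at 0.23 ± 0.18 and 0.22 ± 0.18. In whole lung, a lower glucocorticoid response cannot be told from a change in the share of cell types.

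**Figure D3:**
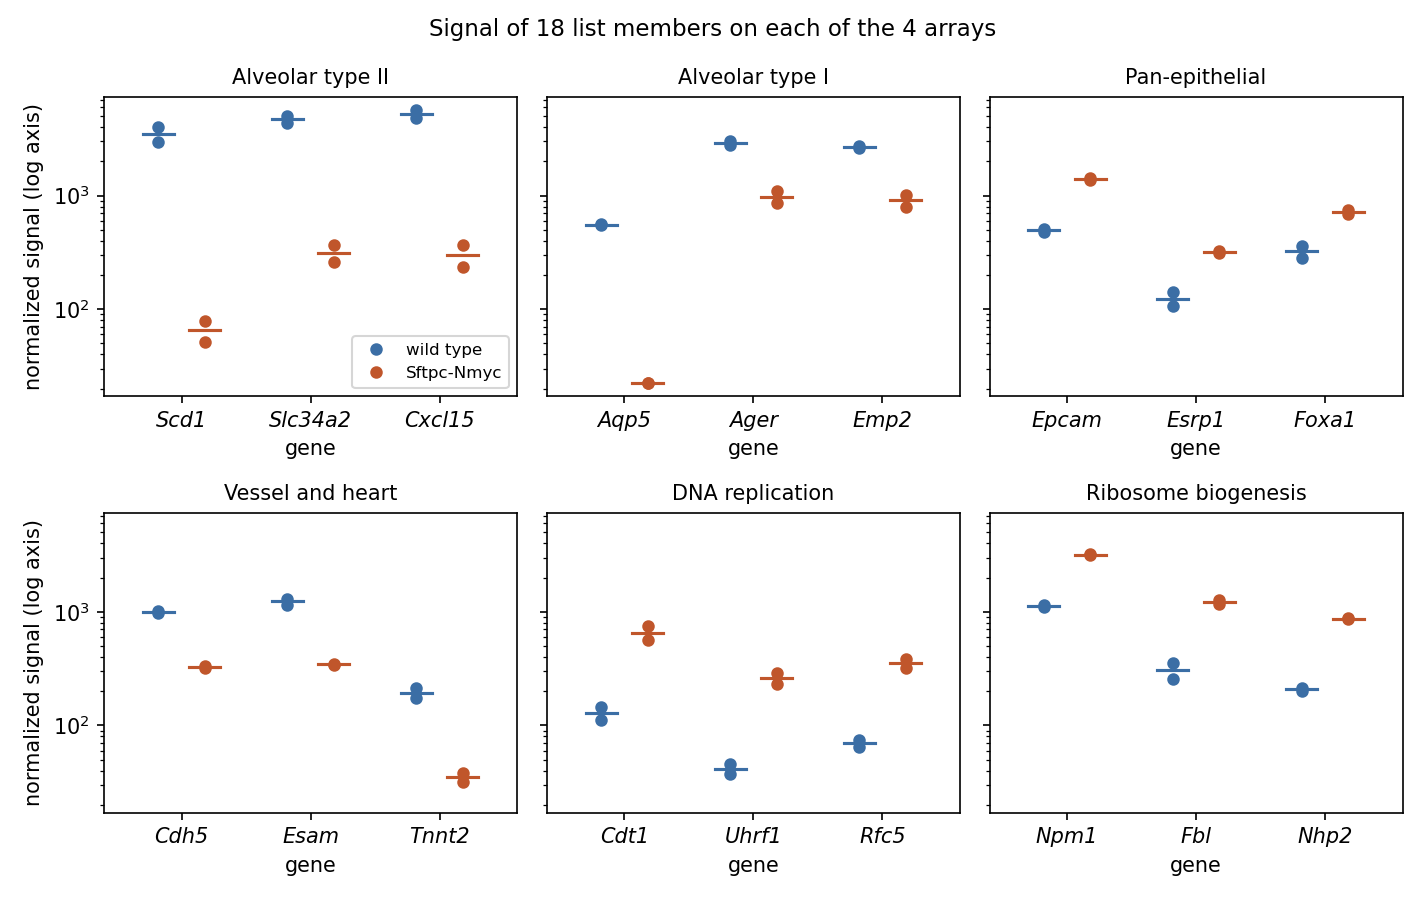
Normalized signal (log axis) of 18 genes from 7 lists, each point 1 array and each short line the group mean, with wild type in blue and Sftpc-Nmyc in orange. Scd1 lies at a mean of 3513 in wild type and 65.3 in the transgenic lungs, and Npm1 at 1129 and 3192.

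The pan-epithelial median exceeded the alveolar type II median by 3.04 and the type I median by 1.5 (two-sided permutation p = 0.00014 and 0.00016, both 0.00024 adjusted over the 6 comparisons). In the pan-epithelial list 7 of 17 were higher and none lower (9 and 1 adjusted over the list alone), with a median of 0.36, a limma camera adjusted p of 0.0025 and an adjusted p = 0.31 with an estimated correlation. Esrp1, an epithelial splicing factor, rose by 1.36 ± 0.18, Foxa1, a transcription factor of endoderm, by 1.15 ± 0.16 and Cdh1, E-cadherin, by 0.99 ± 0.17. Prom1 and Krt19 went against the list without passing, at -0.50 ± 0.16 and -0.24 ± 0.12. Cldn6, a claudin of embryonic epithelia, was among the 12 largest rises at 2.78 ± 0.17. Club and airway secretory genes went both ways, with 3 of 12 higher and 6 lower (4 and 6 adjusted over the list alone), and as a list did not pass (median -0.41, limma camera adjusted p = 0.26). That list did pass without transgenic replicate 1, at a limma camera adjusted p of 0.040. Scgb3a2, a secretoglobin, fell by 0.61 ± 0.08 and Cbr2, a carbonyl reductase, fell by 1.16 ± 0.20. The type II median differed from the club cell median by -2.27 (two-sided permutation p = 0.0023, 0.0027 adjusted over the 6 comparisons). Distal tip progenitor genes did not pass as a list (median -0.31, limma camera adjusted p = 0.13). Of 15, none was higher and 5 were lower (1 and 5 adjusted over the list alone), among them Etv5 at -1.30 ± 0.21 and Bmp4 at -0.92 ± 0.16. That share is near the 30.4% called over all genes tested. Igf2bp1 and Foxp2 went the other way without passing, at 0.76 ± 0.26 and 0.63 ± 0.23. Of 19 members measured, those left out were dim, among them Sox9, named outside the rule, at deposited signals of 5.3 to 50.6. With genes under the 50th percentile left out, the distal tip list passed at a limma camera adjusted p of 0.029. Ciliated genes (1 of 9 higher, none adjusted over the list alone, median 0.30) and neuroendocrine genes (1 of 5 lower, also adjusted over the list alone, median -0.37) did not pass as lists, with limma camera adjusted p of 0.28 and 0.26.

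Genes of the other cell types of the lung were lower. Of 21 endothelial genes 19 were lower and none higher, also adjusted over the list alone (median -1.31, limma camera adjusted p = 1.4e-12, and adjusted p = 0.31 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, fell by 1.59 ± 0.13 and Esam, another junction molecule, fell by 1.82 ± 0.13. Of 20 fibroblast and mesenchyme genes 17 were lower and none higher (18 and 1 adjusted over the list alone), with a median of -0.94, a limma camera adjusted p of 1.7e-09 and an adjusted p = 0.31 with an estimated correlation. Postn, a matrix protein, fell by 1.94 ± 0.15 and Col3a1, a fibrillar collagen, fell by 0.94 ± 0.10. Smooth muscle genes were lower in 5 of 8 and mesothelial genes in 4 of 6, with none higher (6 and 5 adjusted over the list alone), with limma camera adjusted p of 0.0020 and 0.0026 and adjusted p = 0.33 with an estimated correlation for both. Mylk, myosin light chain kinase, fell by 1.10 ± 0.16 and Msln, mesothelin, fell by 2.14 ± 0.32. Macrophage and monocyte genes were lower in 9 of 16, with none higher (11 adjusted over the list alone), with a median of -0.88, a limma camera adjusted p of 6.7e-05 and an adjusted p = 0.31 with an estimated correlation. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 1.32 ± 0.14. Cardiac muscle genes were lower in 11 of 15, with none higher (12 adjusted over the list alone), with a median of -2.24, a limma camera adjusted p of 2.4e-06 and an adjusted p = 0.33 with an estimated correlation. Tnnt2, cardiac troponin T, fell by 2.31 ± 0.21 and Myl4, an atrial myosin light chain, fell by 2.24 ± 0.25.

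Blood cell lists were lower too. Neutrophil genes were lower in 4 of 10 (5 adjusted over the list alone), platelet and mast cell genes in 3 of 7 and erythroid genes in 3 of 5 (both also adjusted over the list alone), with none higher. Their limma camera adjusted p were 0.0081, 0.041 and 0.015, and adjusted p = 0.31, 0.33 and 0.33 with an estimated correlation. Lcn2, lipocalin 2, which epithelium also makes, fell by 2.89 ± 0.29 and Alas2, which starts heme synthesis in red cells, fell by 2.44 ± 0.13. With no filter on dim genes the neutrophil list did not pass, at a limma camera adjusted p of 0.065. The platelet and mast cell list did not pass without wild-type replicate 1 (limma camera adjusted p = 0.11) or without transgenic replicate 2 (0.080).

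Several signalling target lists were lower. The glucocorticoid response, FGF, Wnt and interferon medians lay near -1.01, the pooled median of the vascular, stromal, smooth muscle, mesothelial and myeloid lists. In whole lung, lower signalling cannot be told from a smaller share of such cells. Of 7 genes induced by FGF signalling 4 were lower (5 adjusted over the list alone) and none higher, with a median of -1.10, a limma camera adjusted p of 0.00068 and an adjusted p = 0.33 with an estimated correlation. Spry1 and Dusp6, feedback inhibitors of that pathway, both fell (-1.21 ± 0.13 and -1.84 ± 0.23). Of 8 Wnt target genes 5 were lower and 1 higher, also adjusted over the list alone (median -1.26, limma camera adjusted p = 0.020, and adjusted p = 0.33 with an estimated correlation). Axin2 and Nkd1, negative regulators induced by Wnt, both fell (-1.34 ± 0.16 and -1.89 ± 0.17). The Wnt list did not pass without wild-type replicate 1 (limma camera adjusted p = 0.055) or with the mean of a gene's probe sets (0.060). Interferon response genes were lower in 6 of 7 and none higher, also adjusted over the list alone (median -1.15, limma camera adjusted p = 0.00083, and adjusted p = 0.31 with an estimated correlation), with Rsad2, an antiviral enzyme, at -1.75 ± 0.23. Immediate early genes were lower in 6 of 15 and none higher (7 adjusted over the list alone), with a median of -0.44, a limma camera adjusted p of 0.021 and an adjusted p = 0.33 with an estimated correlation. Jun fell by 1.39 ± 0.14 and Fos fell by 1.32 ± 0.21, while Egr1 stood at 0.60 ± 0.26 without passing. The immediate early list did not pass without wild-type replicate 2 (limma camera adjusted p = 0.059) or with no filter on dim genes (0.11).

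The lists for Notch, Hedgehog, p53, hypoxia, glycolysis, cholesterol synthesis, heat shock, the unfolded protein response and the circadian clock did not pass with limma camera. Their medians lay between -0.31 and 0.21, and limma camera adjusted p lay between 0.21 and 0.93. Glycolysis genes were higher in 6 of 14 and lower in 2, heat shock genes higher in 4 of 9 and lower in 3, p53 targets higher in 2 of 12 and lower in 4, and hypoxia genes higher in 2 of 14 and lower in 2, all with the same counts adjusted over the list alone. Unfolded protein response genes were higher in 1 of 16 and lower in 4, and Notch genes higher in 1 of 13 and lower in 4, again with the same counts adjusted over the list alone. Cholesterol synthesis genes were higher in 2 of 14 (0 adjusted over the list alone), Hedgehog targets lower in 2 of 6 (1 higher and 2 lower adjusted over the list alone), and circadian genes higher in 1 of 11 and lower in 1 (0 and 1 adjusted over the list alone). Within them, Ldha, lactate dehydrogenase A, rose by 0.93 ± 0.10, the mitochondrial chaperones Hspd1 and Hspe1 rose by 1.49 ± 0.13 and 1.54 ± 0.13, and Asns, asparagine synthetase, rose by 1.56 ± 0.16. In all, 24 of 39 lists tested passed, 7 higher and 17 lower, and with an estimated correlation 0 of 39 passed in limma camera, with a lowest adjusted p = 0.31 and a lowest unadjusted p = 0.010. By limma's fry, 20 of the 24 passed. Heat shock, the unfolded protein response and ciliated genes passed by fry and not by camera, at limma fry adjusted p of 0.041, 0.026 and 0.044. The exceptions among the 24 were cardiac muscle, immediate early, platelet and mast cell, and G2/M, at limma fry adjusted p of 0.050, 0.050, 0.055 and 0.089.

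Among single genes, the 12 largest rises were led by Mtm1, a myotubularin phosphatase, at 5.05 ± 0.16, for which the third probe set stayed at signals of 23.9 to 28.1 on all 4 arrays. They also held Exosc1 (3.26 ± 0.28), an exosome subunit, Rrp9 and Ppan (3.19 ± 0.31 and 2.97 ± 0.48), both ribosome assembly factors, and E2f8, Dtl, Ung and Dut (2.91 ± 0.37, 2.89 ± 0.28, 2.57 ± 0.34 and 2.54 ± 0.21), which act in cell cycle control or DNA synthesis and repair. The largest falls included Napsa (-4.27 ± 0.27), a protease that processes surfactant protein, Retnla (-4.15 ± 0.24), a secreted resistin-like protein, and Lyz1 (-3.93 ± 0.11), a lysozyme. Acy1, Nkain1, Pgam2, Pon1 and Il33 complete both sets, at 2.68, 2.50, -3.87, -3.63 and -3.23. Where the lower of the 2 groups lay below the Bacillus controls, the size of the fold depends on the offset added before taking logarithms.

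Sex-linked and technical signals differed between the groups beside all of these lists. Xist, the X-inactivation transcript, fell by 4.56 ± 0.15, with all 3 of its probe sets lower in both transgenic lungs. Of 6 probe sets for the Y-linked genes Eif2s3y, Kdm5d and Uty, named after their values were seen, 5 were higher in both transgenic lungs, and the labels give no sex. Over autosomal genes alone, a setting added after these values were seen, 2575 genes differed. Leaving out the sex chromosomes does not remove effects of sex on other genes, so this count does not separate sex from genotype. The control probe set for B1 repeats read 846 and 1019 in wild type and 2072 and 1712 in the transgenic lungs, and that for the 5' part of 18S ribosomal RNA read 995 and 1171 against 535 and 596. The 3' to 5' signal ratio of actin was 0.949 and 1.01 in wild type and 1.09 and 1.12 in the transgenic lungs, and that of Gapdh 1.05 and 0.927 against 0.843 and 0.912.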

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

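Probe sets that entered no test, because they are controls or the annotation gives them several symbols or none, were searched for signals at least 3 times the highest wild-type signal and the highest Bacillus control on both transgenic arrays. The factor of 3 was set after the signals had been seen. The search found 9 probe sets, whose log2 changes are from deposited signals with the offset of 5 and without normalization between arrays, and no test was made. Of those with no symbol, probe set 1434279_at was higher by 3.94, 1434280_at by 3.51, 1416184_s_at by 2.64 and 1415851_a_at by 1.77. Of those with several symbols, probe set 1417823_at was higher by 4.38, 1426657_s_at by 4.23, 1456471_x_at by 2.59, 1415912_a_at by 2.41 and 1448563_at by 1.68. The highest signals were those of 1415912_a_at, at 4677 and 4918 in the transgenic lungs against 834.1 and 971 in wild type.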

How the results depend on the processing

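With 1 value per gene, Mycn rose in each alternative (3.0 to 3.6, and 0.97 with the mean of its probe sets), and no gene called in both the chosen setting and such an alternative changed direction. Over all probe sets, 4 called genes, Mycn among them, had another probe set called the other way. Counts moved by over 1.5 times in several cases. Over all probe sets, where more units were tested, there were 4056 calls (2110 higher). A 2-fold minimum gave 1002 (480 higher, 522 lower), and camera with an estimated correlation gave 0 lists (0 higher, 0 lower). Some counts of genes also moved that far when either wild-type array or transgenic replicate 2 was left out. Leaving out 1 array gave 1375 to 1899 genes, 718 to 875 higher and 657 to 1024 lower, with the lone array assumed to vary like the other group. The replicate number as a block gave 2218 genes, 2178 of them shared with the unblocked fit, and the same count of 24 lists. The replicate differences of the groups correlated at -0.043 over genes, and with 2 pairs and no stated pairing the numbers were not used. Mt1, not called at 0.23, was called at -0.54 with the mean of its probe sets; the cause was not tested. List results kept their call in 648 alternatives, gained it in 5 and lost it in 35, of which 24 were with the estimated correlation. Named genes kept theirs in 3137, gained in 21 and lost in 164. Among the normalizations, the median of all genes moved by under 0.1 and the share of higher calls by under 10 points. Of the settings added after the data were seen, autosomal genes gave 2575 calls and genes above the Bacillus controls 2670. Dim signals limit the sizes of folds, as no detection calls were used.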

Other observations

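Further lists, of mitochondrial import and chaperone genes and of imprinted genes, were chosen after the values were seen, as were the genes named from them, so their tests are not independent evidence. Of 22 tested genes of mitochondrial import and chaperoning, 15 were higher and 0 lower in the transgenic lungs, with a median log2 fold change of 0.74 (68.2% called, against 30.4% of all genes tested; limma camera adjusted p = 2.6e-09 over these 2 lists, and adjusted p = 0.071 with an estimated correlation). Timm8a1, a carrier of the intermembrane space, rose by 2.14 ± 0.17 (log2, SE; limma adjusted p = 0.00037), Hspa9, the matrix chaperone, by 2.06 ± 0.16 and Atad3a, an inner membrane ATPase, by 1.99 ± 0.16. Of 16 tested imprinted genes 4 were higher and 7 lower (median -0.57, limma camera adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation). Among them fell the noncoding transcripts Meg3 (-2.87 ± 0.14) and Rian (-2.24 ± 0.18) and the Notch ligand homologue Dlk1 (-1.67 ± 0.10). Of 5 Meg3 probe sets 4 fell, and 1436057_at stood at -0.11 ± 0.26. Igf2, a growth factor, rose by 1.08 ± 0.11 and Cdkn1c by 1.19 ± 0.13. Dlk1 is also on the alveolar type II list.

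The tests in the following paragraphs were chosen after the result was seen, except that of the genes near Mtm1. Those of X-chromosome dosage and of growth transcripts replaced first versions that could not separate the explanations well. The first pattern is the separation of the groups by sex-linked signals. It fits wild-type embryos that were female and transgenic embryos that were male: the median log2 fold change over 6 Y-linked probe sets was 1.88. These probe sets are part of the pattern itself, so their median is no independent test. Whether direct X-chromosome dosage adds calls among X-linked genes stays open: 26.6% of these were called against 30.5% of autosomal genes (two-sided Fisher's exact p = 0.19). A sex difference in lung maturation also stays open for the alveolar lists, since 0 genotype differences could be fitted within 1 sex and sex and genotype cannot be told apart in these 4 lungs. The transgene is the biological explanation the design names, and it is untested against sex or a difference in age.

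The second pattern is Mtm1, where probe sets 1434278_at and 1454904_at rose by 5.05 and 5.51 and the third, 1416934_at, did not. A regional change on the X chromosome is argued against: the 10 nearest tested genes had a median of -0.057, although Hmgb3, named after its value was seen, rose by 0.93. A rise of the full transcript stays open, because the third probe set changed by 0.17 at signals below the Bacillus controls. Hybridization of RNA made from the transgene construct is a candidate explanation too: from transgenic replicate 1 to 2 the changes of the Mtm1 and Mycn probe sets differed by 0.13, but 2 arrays are too few to tell, and probe sequences were not used here.

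The third pattern is the joint fall of lists for non-epithelial cells beside higher pan-epithelial genes. Growth transcripts that lower all other genes alike stay open as a part of these falls, but do not cover their whole size. The 150 tested genes of 14 response and metabolic lists, none of them on a cell type or growth list, had a median of -0.28. This lay above the pooled median of the vascular, stromal, smooth muscle, mesothelial and myeloid lists by 0.74 (two-sided permutation p = 1e-05, the smallest possible). It lay above that of 8 lists, with neutrophil, platelet and mast cell, and erythroid genes added, by 0.68 (two-sided permutation p = 1e-05). The lists compared were picked after their falls were seen, so these p-values carry little weight. The median over all 8675 tested genes was -0.021 after normalization, which gives the arrays 1 distribution, so this value cannot show a shift of all genes. A single dilution, as a larger share of epithelium could give, does not cover cardiac muscle, whose median differed from that of the 5 lists by -1.22 and from that of the 8 by -1.28 (two-sided permutation p = 1e-05 and 2e-05), with Myl4 at normalized signals of 355 in wild type and 69.4 in the transgenic lungs. In the pooled lists Krt19, also on the pan-epithelial list, was left out, and the mesothelial median, -1.23 with it, became -1.35. Permutation here counts genes that move together as independent. A single dilution of all 8 lists stays open: their medians ran from -1.35 to -0.37, a gap of 0.98 (permutation p = 0.0486 over 92 genes). That p-value is unadjusted, and the upper end is the platelet and mast cell list of 7 genes. For the 5 lists a single dilution also stays open, with a gap of 0.52 (permutation p = 0.12) around a pooled median of -1.01 over 70 genes. The smaller gap depends on leaving out the 3 blood cell lists, a choice made after the medians were seen. A difference in the amount of heart muscle taken with the lung, or a change within these cell types, was not tested.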
